A study of Homo sapiens with 23 samples.

How the data were processed

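Bulk RNA sequencing of natural killer (NK) cells from human cord blood was analysed in 9 libraries. The labels name 3 groups of 3 libraries, Cas9 (cells with the nuclease and no named target), TET2 KO and DNMT3A KO, and give each library the number of its cord blood, 1, 2 or 3. Another 14 samples of the series, single-cell libraries of bone marrow, were not analysed here.

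The deposited table holds whole-number counts per gene symbol, not normalized, and its columns carry the names given in the labels. The authors' aligner, gene counter, annotation and strand setting for this table are not given in the sources used here. The submitters' processing notes name the genome build GRCh38 (hg38), Cell Ranger 7.2.0 and Seurat 5.1.0 without saying which data each served. The protocol in the labels describes cells purified by flow sorting and a droplet single-cell kit, which is shared with the single-cell samples and was not taken to describe the bulk libraries. Since strand is not stated, a gene and an overlapping or antisense partner cannot be told apart, and genes with near-identical copies (HBG1 and HBG2, HBA1 and HBA2, the KIR and HLA families, histone genes) may share reads, so their single values are uncertain.

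Of 33952 symbols, 33072 were found in GENCODE 29. Symbols on the Y chromosome alone and the X inactivation transcripts, 61 in all, were left out throughout. Counts were filtered with edgeR's filterByExpr, which left 17091 genes, and scaled by TMM factors. The libraries held 26788593 to 38953883 counts, so that 3 counts corresponded to 0.0795 to 0.113 CPM (counts scaled to library size). These limits cover counting error only. Replicate libraries of a group differed by far more than counting noise (chi-square per degree of freedom of 44.4 to 294), so none was counted as a duplicate.

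The main test was edgeR's quasi-likelihood F test in 1 fit over the 9 libraries without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change over the root of F. Log2 CPM used a prior count of 2. Gene lists, 34 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists within a comparison, and again with the correlation estimated from the data, and with fry. The groups, tests, covariates, gene lists, the rule for naming genes and a first set of other settings were fixed before the data were examined. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

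The rule for naming genes took TET2 and DNMT3A in every case, then genes that passed the threshold in the main test or in the test with the cord blood as a block with 1 sign in all 3 cord bloods. No gene passed either test, so up to 2 members of each list with the highest mean level were named. KIR and HLA genes were summed over a family and given per group. EGR1, FOS, SPP1, PRAME, CCL3, GATA1, SDK2, CNOT1, ARHGAP31, CKAP5, HEATR5B, OGT, LMO2 and TRIM58 are named outside the rule or with further values, and were chosen after their values were seen.

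The cord blood numbers in the labels pair the libraries, because libraries with the same number come from the same cord blood. Deviations from the group means were compared between libraries of the same cord blood: 5 of the 9 pairs correlated above 0.1, with r from -0.468 to 0.827 and a median of 0.207 across genes. The settings fixed at that time were a fit with the cord blood as a block, DESeq2 with and without that block, limma with trend, RLE and upper-quartile scaling, no filter and a strict filter on low counts (at least 10 counts in 3 libraries and a mean of at least 5 CPM), the 6 libraries of a comparison alone, other thresholds, and leaving out each library and each cord blood.

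Further fits were chosen after the data had been seen. The first used a GC-window score: for each gene, the highest GC share of any 100-base window of its median-length coding transcript was taken (of any transcript where none is coding), and the score of a library is the mean log2 deviation of 579 expressed genes with a window of 85 percent GC or more, minus that of 3515 with no window of 70 percent. Of the 17091 genes, 16749 had a window value. Others added a marker score from the erythroid and K562 line list or from 7 genes picked while the data were explored, offsets from a curve on gene GC content and length, or left out genes with a window of 75 percent GC or more. The score is made from the same libraries that it adjusts.

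The tests were checked on simulated counts for TET2 KO against Cas9 over 17091 genes, with 100 genes seeded at each fold. Where libraries varied at random, the fit without covariates recovered 10% of genes seeded at 2-fold and 70% at 4-fold, with 4 false calls, the block 1% and 44% with 3 false calls, and the score with the block 0% of either. Where libraries kept the cord blood and GC-window differences of the data, the fit without covariates recovered 18% and 73%, the block 21% and 87%, and the score with the block 95% and 100%, the last with 16 false calls. That simulation holds the differences that the score and the block describe. The higher recovery of the score with the block there was thus built in. In a further simulation over the same genes, 1 list moved by 2-fold was called (adjusted p = 2.01e-21; adjusted p = 0.00102 with an estimated correlation) and 0 of the other 33 lists were. Its genes were drawn independently, so it cannot show how often lists of correlated genes are called falsely. In the data, estimated correlations ran from -0.0405 (ILC3 genes) to 0.927 (myeloid markers). They were 0.785 for mitosis and 0.573 for mitochondrial genes.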

Results

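The data were bulk RNA-seq counts of cord blood NK cells, innate lymphocytes that kill infected and transformed cells. TET2 encodes an enzyme that oxidises methylated cytosine and DNMT3A encodes a DNA methyltransferase. Each was knocked out in cells of 3 cord bloods, with Cas9 cells of the same 3 cord bloods as controls. Total counts per library were 37782281, 26788593 and 26813700 in Cas9, 28430068, 37559580 and 29672231 in TET2 KO, and 28255482, 29109591 and 38953883 in DNMT3A KO, for cord bloods 1, 2 and 3.

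The targeted genes were examined first. TET2 lies on chromosome 4 from 105145875 to 105279816 on the plus strand, and DNMT3A on chromosome 2 from 25227855 to 25342590 on the minus strand (GRCh38). The counts cover whole genes, and the cut sites are not given in the sources used here. TET2 measured 65.2 ± 14.7 CPM in Cas9 and 51.2 ± 7.66 CPM in TET2 KO (SD, n = 3 each), a log2 fold change of -0.35 (SE 0.21), with lower values in TET2 KO in 3 of 3 cord bloods (-0.26, -0.26 and -0.49). DNMT3A measured 50.5 ± 5.68 CPM in Cas9 and 37.7 ± 5.66 CPM in DNMT3A KO (SD, n = 3 each), a log2 fold change of -0.42 (SE 0.22), also lower in 3 of 3 cord bloods (-0.86, -0.21 and -0.22). The values rest in part on single libraries. TET2 was at -0.17 without the Cas9 library of cord blood 3. DNMT3A was at -0.31 without the DNMT3A KO library of cord blood 1 and -0.24 without that cord blood. Neither difference passed edgeR's quasi-likelihood test (adjusted p = 1 for both). In the other knockout, TET2 stood at 61.6 ± 11.6 CPM in DNMT3A KO and DNMT3A at 49.4 ± 13.1 CPM in TET2 KO (SD, n = 3). By cord blood, TET2 differed from Cas9 by 0.11, 0.22 and -0.55 in DNMT3A KO, and DNMT3A by -0.72, 0.26 and 0.27 in TET2 KO. In the cord blood where each target fell most in its own knockout, it thus fell by a similar amount in the other. Small insertions or deletions need not lower a transcript, so these levels do not measure editing.

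**Figure D1:**
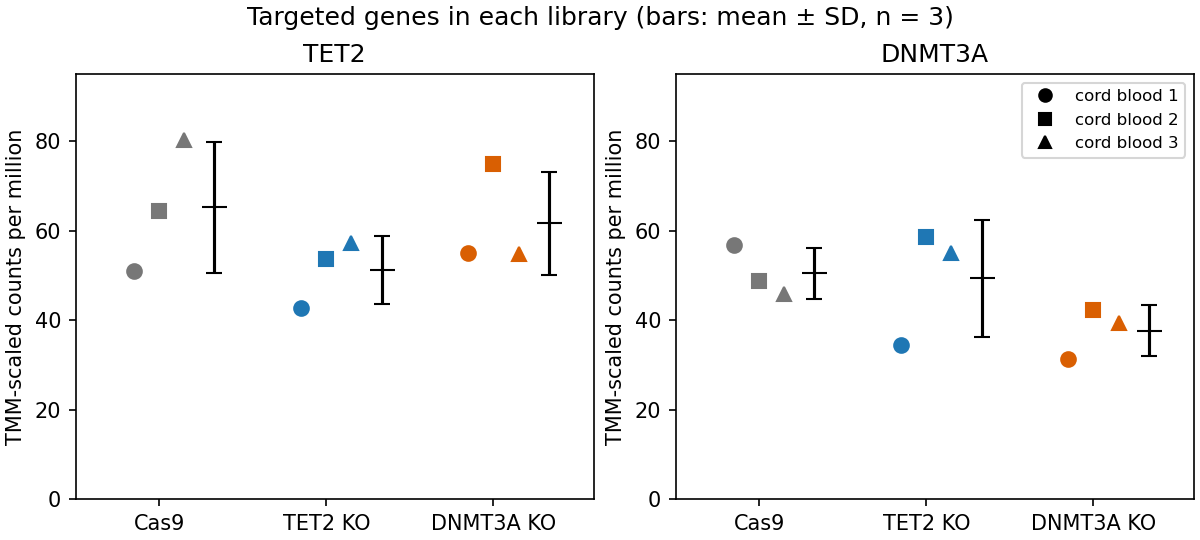
TMM-scaled levels (CPM) of TET2 (left) and DNMT3A (right) in each library, by group, with symbols for the 3 cord bloods and bars for the mean ± SD of 3 libraries. TET2 was at 42.7, 53.7 and 57.4 in TET2 KO and 51.1, 64.3 and 80.3 in Cas9, in the order of the cord bloods.

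The comparison of TET2 KO with Cas9 asks how loss of TET2 alters the NK cell transcriptome. Genes of mitosis had a median log2 fold change of -0.41, with 1 of 30 members above 0. The median was -1.11, 0.46 and -0.37 in cord bloods 1, 2 and 3, and the list fell by limma's camera (adjusted p = 2.42e-05; adjusted p = 0.824 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, had a log2 fold change of -0.49 (SE 0.47), and MKI67, a proliferation marker, of -0.03 (SE 0.54). Mitochondrially encoded genes fell as a list, with 0 of 16 members above 0 and a median of -0.20 (-0.07, -0.13 and -0.36 in the 3 cord bloods; adjusted p = 0.000234; adjusted p = 0.709 with an estimated correlation). MT-RNR2, a ribosomal RNA, measured -0.34 (SE 0.31) and MT-CO1, a subunit of cytochrome oxidase, -0.14 (SE 0.27; 0.18, -0.15 and -0.32 in the 3 cord bloods). The mitochondrial share of all counts did not fall in cord blood 1 (0.577% in Cas9 and 0.613% in TET2 KO). Over the 9 libraries it ran against the GC-window score, the level of genes with GC-rich windows relative to others, which was chosen after the data were seen (r = -0.821; -0.279 for the median level of the list, which had an r of -0.838 with the score of the erythroid and K562 line markers). With that score and the cord blood in the fit the list median was -0.18 (adjusted p = 0.000106; 0.709 with an estimated correlation). The mitosis call was lost without the Cas9 library of cord blood 1 (median 0.08) or the TET2 KO library of cord blood 3 (-0.18), and the mitochondrial call without the Cas9 library of cord blood 2 (-0.08) or the TET2 KO libraries of cord bloods 1 (-0.11) or 3 (-0.16).

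NK cytokines and chemokines rose as a list in TET2 KO, with 19 of 21 members above 0 and a median log2 fold change of 0.22 (0.49, 0.09 and 0.31 in the 3 cord bloods; camera adjusted p = 0.000463; adjusted p = 0.579 with an estimated correlation). The chemokine CCL5 was at 3413 ± 173 CPM against 3305 ± 422 CPM in Cas9 (SD, n = 3 each), and LTB, which encodes lymphotoxin beta, had a log2 fold change of 0.09 (SE 0.46). CCL3, another chemokine, was higher in 3 of 3 cord bloods at 0.39 (SE 0.14; edgeR adjusted p = 1). Immediate early genes, which respond within minutes to receptor signals, rose as a list with a median of 0.25 (-0.14, 0.44 and 0.67; adjusted p = 0.000463; adjusted p = 0.579 with an estimated correlation). Its most abundant members, KLF6 and BTG2, measured -0.02 (SE 0.26) and 0.14 (SE 0.17), and EGR1, a transcription factor gene, 1.27 (SE 0.79; -0.99, 1.73 and 2.88 in the 3 cord bloods). The level of the immediate early list followed the GC-window score over the 9 libraries (r = 0.908). Of its 23 members, 17 have a window of 75 percent GC or more. Without such genes, which leaves 6 members, and with the cord blood as a block the median was 0.205 and the call was lost (adjusted p = 0.129). With the score and the block it was 0.27 (adjusted p = 1.52e-05; 0.709 with an estimated correlation). With GC and length offsets it was 0.208 (adjusted p = 0.00105). The cytokine call was lost without the Cas9 library of cord blood 1 (median -0.03), and the immediate early call without the Cas9 or the TET2 KO library of cord blood 3 (0.13 and 0.19).

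Cytotoxic effectors rose as a list with 18 of 20 members above 0 and a median of 0.10 (0.27, 0.11 and -0.0075 in the 3 cord bloods; adjusted p = 0.00828; adjusted p = 0.73 with an estimated correlation). GNLY, which encodes the pore-forming protein granulysin, had a log2 fold change of 0.27 (SE 0.14), and PRF1, perforin, of 0.03 (SE 0.14). Antigen presentation rose with a median of 0.11 (0.24, 0.17 and -0.0071; adjusted p = 0.00615; adjusted p = 0.579 with an estimated correlation), and its member B2M measured 0.09 (SE 0.26). The IL-2 and STAT5 response list had a median of 0.09 (0.12, 0.10 and 0.23; adjusted p = 0.0165; adjusted p = 0.579 with an estimated correlation), with the receptor subunits IL2RB at 0.02 (SE 0.22) and IL2RG at 0.12 (SE 0.25). Oxidative phosphorylation (nuclear genes) had a median of 0.10 (0.09, 0.23 and -0.04; adjusted p = 0.00164; adjusted p = 0.824 with an estimated correlation), with the ATP synthase genes ATP5B at 0.03 (SE 0.10) and ATP5A1 at -0.03 (SE 0.13). Unfolded protein and amino acid stress had a median of 0.08 (0.06, 0.03 and 0.15; adjusted p = 0.0318; adjusted p = 0.579 with an estimated correlation), with the chaperone gene HSPA5 at 0.09 (SE 0.14). Each of these 5 calls was lost without 1 of several libraries: cytotoxic effectors and antigen presentation without Cas9 1 (medians 0.10 and 0.06), TET2 KO 1 (0.13 and 0.11) or TET2 KO 2 (0.08 and 0.09), where the digit is the cord blood. The IL-2 call was lost without Cas9 1 (0.13), Cas9 3 (0.08), TET2 KO 2 (0.05) or TET2 KO 3 (0.09), oxidative phosphorylation without Cas9 2 (0.05), TET2 KO 1 (0.08) or TET2 KO 2 (0.06), and the stress list without Cas9 2 (0.09), Cas9 3 (0.04) or TET2 KO 1 (0.03). The IL-2 level followed the GC-window score (r = 0.663), and 16 of 24 members have a window of 75 percent GC or more. Its call was also lost without such genes and with the block, with GC and length offsets and with the score alone. It was kept with the score and block (adjusted p = 0.0441). Oxidative phosphorylation lost its call with the score and block (median 0.07, adjusted p = 0.0575). The stress call was lost with upper-quartile scaling, with no filter and with the offsets.

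Of the 9 lists called in TET2 KO, 4 kept 1 sign of the median in all 3 cord bloods, and fry, a rotation test, called 0 of the 34. Over the 9 libraries, NK cytokines (r = -0.743), antigen presentation (-0.674), cytotoxic effectors (-0.555) and the IL-2 list (-0.437) ran against the erythroid and K562 line marker score. The stress list followed it (0.668). In cord blood 1, where NK cytokines rose most, summed markers were lower in TET2 KO (390.4 CPM) than in Cas9 (1095 CPM). In cord blood 3 the cytokine list and the markers both rose. Fits with a marker score or sum kept the cytokine call. The fit with GC and length offsets, the 7-gene marker sum and the block lost the calls of cytotoxic effectors, antigen presentation and mitosis. It also lost those of the IL-2 list and oxidative phosphorylation. These 2 calls were further lost with the GC-window score, marker score and block, and with the offsets, 7-gene score and block. The stress call was lost with the GC-window score, 7-gene score and block. The other 25 lists did not pass camera. With the cord blood as a block KIR genes (adjusted p = 0.00183), the type I interferon response (0.0132), tissue residency (0.039) and the NF-kB response (0.0475) passed, all upward (0.582 to 0.66 with an estimated correlation). Among them, the tissue residency and TGF-beta response had a median of 0.11 (adjusted p = 0.0686), and summed KIR counts, from receptors of NK cells for HLA, were 1750 ± 902 CPM against 1544 ± 725 CPM in Cas9 (SD, n = 3 each). The erythroid and K562 line markers had a negative median of -1.54 and a mean of -1.52, while camera's direction was up (adjusted p = 0.79).

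No single gene passed in TET2 KO: edgeR and limma each called 0 of 17091 genes. They gave 99 and 96 genes at an unadjusted p under 0.05, where chance alone gives 855 for 17091 genes. DESeq2, run on all genes with any count, called 0, with 216 at an unadjusted p under 0.05. Counts so far below 855 mean that the p-values were not spread evenly, so 0 calls do not show that no gene changed. Members called over all genes tested numbered 0 in each of the 34 lists, and 0 adjusted over the list alone. With cord blood 1 left out, edgeR called 290 genes, all higher in TET2 KO, and 1015 higher and 9 lower with the cord blood as a block; DESeq2 with that block called 15 higher and 68 lower over the 9 libraries.

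**Figure D2:**
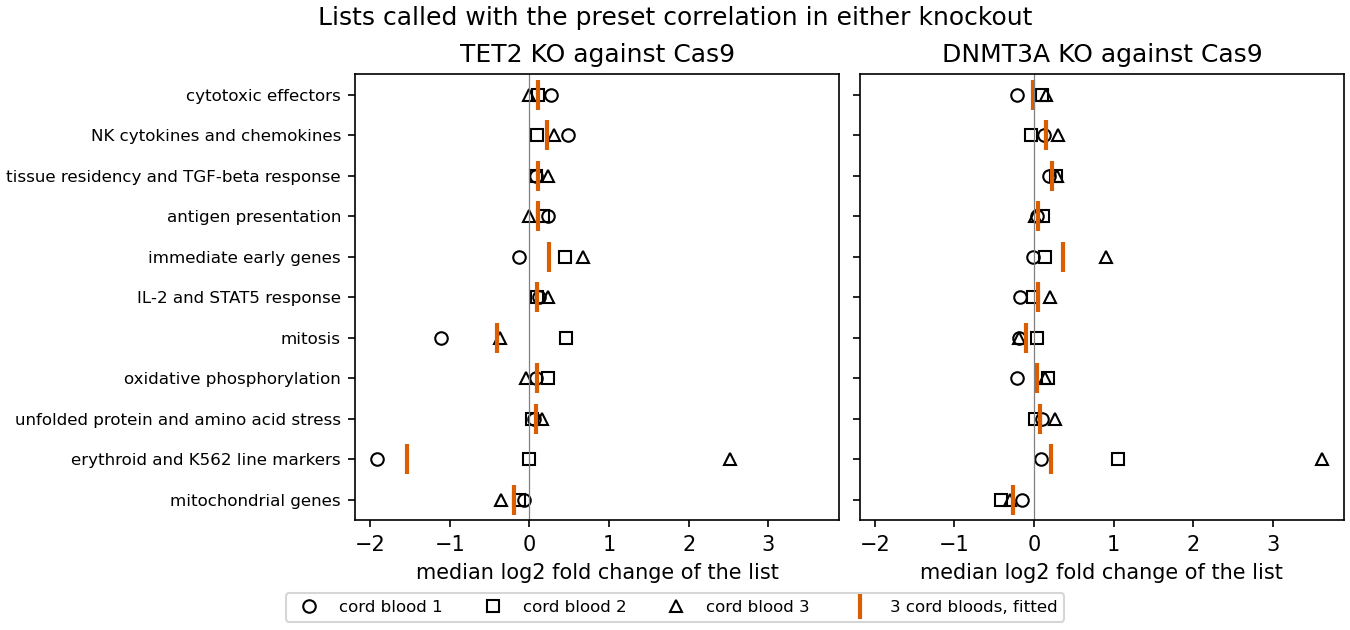
Median log2 fold change of each gene list called by camera at the preset correlation in either knockout, for TET2 KO (left) and DNMT3A KO (right) against Cas9 on a shared axis. Open symbols are the 3 cord bloods and the orange bars the fitted values over all 3; mitosis in TET2 KO ran from -1.11 to 0.46, and mitochondrial genes lay below 0 in all 3 cord bloods in both knockouts.

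The comparison of DNMT3A KO with Cas9 asks the same of DNMT3A. Mitochondrially encoded genes fell as a list, with 1 of 16 members above 0 and a median log2 fold change of -0.26 (-0.15, -0.41 and -0.30 in the 3 cord bloods; camera adjusted p = 8.74e-06; adjusted p = 0.917 with an estimated correlation). MT-RNR2 measured -0.35 (SE 0.31) and MT-CO1 -0.07 (SE 0.27; 0.81, -0.17 and -0.73 in the 3 cord bloods). The mitochondrial share of all counts, which ran against the GC-window score, was higher in DNMT3A KO in cord blood 1 (0.782% against 0.577% in Cas9). It was lower in cord bloods 2 and 3 (0.572% against 0.854%, and 0.525% against 0.787%). With that score and the cord blood in the fit the list median was -0.26 (adjusted p = 1.82e-06; 0.544 with an estimated correlation). Genes of tissue residency and the TGF-beta response rose as a list, with 14 of 20 members above 0 and a median of 0.22 (0.19, 0.27 and 0.29; adjusted p = 0.0108; adjusted p = 0.384 with an estimated correlation). CD69, a surface protein of activated and tissue-resident lymphocytes, was at 744 ± 132 CPM against 598 ± 165 CPM in Cas9 (SD, n = 3 each; log2 fold change 0.32, SE 0.23), and ITGA1, an integrin subunit, measured -0.04 (SE 0.17). The mitochondrial call was lost without the Cas9 library of cord blood 2 (median -0.11) or without cord blood 3. Adding GC and length offsets, the 7-gene marker score and the block lost it too, and it was kept in 31 of 34 alternatives. The level of the mitochondrial list ran against the marker score over the 9 libraries (r = -0.838). The residency call was lost without the Cas9 library of cord blood 3 (0.18) or the DNMT3A KO libraries of cord bloods 1 (0.25) or 3 (0.22). The residency level followed the marker score (r = 0.684) and the GC-window score (0.502). Its call was also lost with no filter and with the GC-window score alone. Either marker score with the GC-window score and block lost it too, as did offsets with the 7-gene score and block. It was kept with the GC-window score and block (median 0.28, adjusted p = 0.0046), and in 24 of 34 alternatives.

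Immediate early genes also rose as a list in DNMT3A KO, with 19 of 23 members above 0 and a median of 0.36 (-0.02, 0.14 and 0.91 in the 3 cord bloods; adjusted p = 0.0106; adjusted p = 0.866 with an estimated correlation). FOS, a transcription factor gene of the list, was higher in 3 of 3 cord bloods (1.86, 0.65 and 0.53), with a log2 fold change of 1.06 (SE 0.36; edgeR adjusted p = 1). DESeq2's Wald test with the cord blood as a block called FOS (log2 fold change 1, adjusted p = 0.0493). EGR1 measured 1.13 (SE 0.78), with -1.08, 1.61 and 2.73 in the 3 cord bloods. This list followed the GC-window score, as given above. Without genes of GC-rich windows and with the block the median was 0.28 and the call was lost (adjusted p = 0.129). With the score and the block it was 0.23 (adjusted p = 5.83e-05; 0.544 with an estimated correlation). Erythroid and K562 line markers (K562 is a leukaemia line with erythroid features) rose as a list, with a median of 0.21 (0.09, 1.06 and 3.62; adjusted p = 0.045; adjusted p = 0.917 with an estimated correlation). The fetal globin genes HBG2 and HBG1 measured 0.41 (SE 2.54) and 0.45 (SE 2.49). The summed markers were at 1095, 28.5 and 36.3 CPM in the Cas9 libraries of cord bloods 1, 2 and 3, 390.4, 32.5 and 89.8 CPM in TET2 KO, and 1265, 34.5 and 176 CPM in DNMT3A KO. In cord blood 2 most of each sum came from EPOR and BLVRB (17.9 and 9.73 CPM in Cas9). Most other members had few or no counts there, so the sum and the list median of that cord blood say little. The immediate early call was lost without the Cas9 or the DNMT3A KO library of cord blood 3 (medians 0.08 and 0.09). The marker call was lost without Cas9 2 (-0.23), Cas9 3 (-0.22), DNMT3A KO 1 (-2.18), DNMT3A KO 3 (0.55) or any TET2 KO library (0.13 each), where the digit is the cord blood.

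Of the 4 lists called in DNMT3A KO, 3 kept 1 sign of the median in all 3 cord bloods, and fry called 0 of the 34. The other 30 lists did not pass camera. With the block germline genes silenced by DNA methylation (adjusted p = 9.46e-07; medians 0.49, 0 and 2.22 in the 3 cord bloods), myeloid markers (3.77e-05), KIR genes (0.00321), B cell markers (0.00321) and the stress list (0.0446) passed upward. S phase passed downward (0.0394; all 6 lists were at 0.523 to 0.911 with an estimated correlation). Over the 9 libraries the levels of the germline, myeloid and B cell lists followed the score of the erythroid and K562 line markers (r = 0.994, 0.983 and 0.944), so their rise was not read as a separate effect of DNMT3A. Mitosis had a median of -0.10 (adjusted p = 0.142), with MKI67 at -0.52 (SE 0.54), and NK cytokines and chemokines were at an adjusted p of 0.105. Summed KIR counts were 1636 ± 586 CPM and summed HLA counts 7666 ± 1500 CPM, against 7912 ± 188 CPM for HLA in Cas9 (SD, n = 3 each). Whether a list that passed in 1 knockout alone differed between them is given by the comparison of the knockouts.

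No single gene passed in DNMT3A KO either: edgeR called 0 of 17091 genes, DESeq2 0 and limma 0, with 112, 223 and 120 genes at an unadjusted p under 0.05. List members called numbered 0 over all genes tested and 0 adjusted over the list alone. With cord blood 1 left out, edgeR called 306 genes higher and 3 lower (CKAP5 -0.78, HEATR5B -1.03 and OGT -0.70, chosen after their values were seen), and 1183 higher and 234 lower with the cord blood as a block; DESeq2 with that block called 14 higher and 45 lower over the 9 libraries.

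TET2 KO was set against DNMT3A KO to ask whether the knockouts differ. Cytotoxic effectors were higher in TET2 KO by a median of 0.09 (0.49, -0.03 and -0.05 in the 3 cord bloods) and mitosis was lower by a median of -0.26 (-0.89, 0.32 and -0.20). Both passed camera at the preset correlation (adjusted p = 0.0496 each; adjusted p = 0.901 each with an estimated correlation), fry called 0 of the 34 lists, and neither list kept 1 sign in all 3 cord bloods. Mitochondrial genes did not differ by the test (adjusted p = 0.463), nor did the residency list (0.413), and the erythroid and K562 line markers were at an adjusted p of 0.0833. With the cord blood as a block those markers passed (adjusted p = 2.78e-07; 0.711 with an estimated correlation), lower in TET2 KO with 0 of 20 members above 0 and medians of -1.87, -0.78 and -0.96 in the 3 cord bloods. In cord blood 2 most members had few or no counts (HBG2 8 in TET2 KO and 17 in DNMT3A KO), so its median adds little. Germline genes (6.34e-08), myeloid markers (0.00118) and histone genes (0.0072) passed with the block too, also lower. T cell markers (0.0175), NK cytokines (0.0257), antigen presentation (0.0312) and the IL-2 list (0.0454) passed as higher (all 8 lists were at 0.711 to 0.753 with an estimated correlation). The histone list also followed the marker score (r = 0.867), as the germline and myeloid lists did. The lists that passed as higher ran against it: NK cytokines (r = -0.743), antigen presentation (-0.674), T cell markers (-0.538) and the IL-2 list (-0.437). Cytotoxic effectors did too (-0.555). These rises were not read as separate from the lower markers of TET2 KO. EdgeR, DESeq2 and limma each called 0 single genes, with 98, 203 and 100 at an unadjusted p under 0.05, while DESeq2 with the cord blood as a block called 32 higher and 60 lower. The cytotoxic and mitosis calls were lost without DNMT3A KO 1 (medians -0.01 and 0.08, where the digit is the cord blood), Cas9 2 (0.09 and -0.25), Cas9 3 (0.09 and -0.25) or TET2 KO 1 (0.09 and -0.13), cytotoxic effectors also without TET2 KO 2 (0.10), and mitosis without TET2 KO 3 (-0.01) or DNMT3A KO 2 (-0.22).

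Across 17091 genes, the fold changes of the knockouts against the shared Cas9 libraries correlated with r = 0.501 and Spearman's rho = 0.487. Simulated unchanged groups of independent libraries sharing those controls gave a mean r of 0.5 (0.475 to 0.53 in 100 simulations), a mean rho of 0.46 and a covariance of 0.205, against 0.0616 measured. The TET2 KO and DNMT3A KO libraries of a cord blood correlated at 0.827, 0.715 and 0.811 after the group means were removed, which the simulation leaves out, so its r is no value of no change for these libraries and the measured r was not read as an effect. Genes are not independent replicates, and the 3 controls could not be split into parts of at least 2. The overlap of called genes was 0 in each direction. Without the Cas9 library of cord blood 1, r was 0.854, and without the TET2 KO library of that cord blood, 0.221.

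The cord bloods differed in the direction of the knockout differences. Over 9217 expressed genes, the TET2 KO minus Cas9 difference of cord blood 1 correlated with those of cord bloods 2 and 3 at r = -0.795 and -0.878, while cord bloods 2 and 3 correlated at 0.78. For DNMT3A KO these values were -0.802, -0.875 and 0.731. Within a cord blood, the differences of the knockouts from their shared Cas9 library correlated at 0.882, 0.859 and 0.95. The cord blood took a median of 36.7% of a gene's variance, the group 7.17% and the rest 48.4%. The rest includes knockout differences that vary between cord bloods. GC-window scores were 0.77, -0.58 and -0.55 in Cas9, -0.53, 0.16 and 0.64 in TET2 KO, and -0.75, 0.09 and 0.73 in DNMT3A KO, in the order of the cord bloods.

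**Figure D3:**
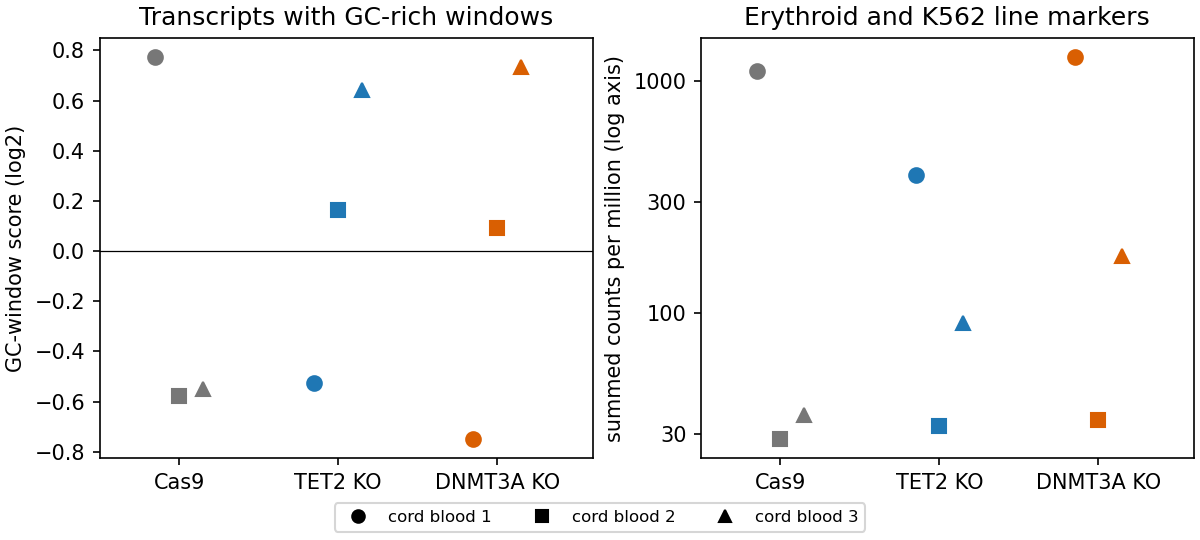
GC-window score (left, log2) and summed erythroid and K562 line markers (right, CPM on a log axis) of each library, by group and cord blood. In cord blood 1 the Cas9 library had the highest GC-window score of its 3 libraries (0.77), and in cord bloods 2 and 3 the lowest (-0.58 and -0.55).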

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

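The fits with a GC-window score, a marker score, GC and length offsets or without GC-rich genes were tests chosen after the results were seen, and the others were planned. TET2 and DNMT3A levels kept their sign in all 35 alternatives, from -0.51 to -0.17 and from -0.74 to -0.24, with lowest adjusted p of 0.298 and 0.35. With the cord blood as a replicate block, edgeR called 0 genes in each comparison (183, 220 and 282 at an unadjusted p under 0.05), and list calls went from 15 to 33. DESeq2 with the block called 83, 59 and 92 genes for TET2 KO, DNMT3A KO and the comparison of the knockouts, and 24 in both knockouts. Leaving out single libraries or cord bloods gave 0 to 290, 0 to 309 and 0 genes, 0 to 267 genes in both knockouts, 7 to 32 list calls and correlations of 0.221 to 0.854. The upper gene counts came without cord blood 1, as did the lowest number of list calls, 7. With the block as well the gene counts were 1024, 1417, 0 and 964, and the correlation without that cord blood was 0.837 with or without the block. The 32 list calls came without cord blood 2 or its DNMT3A KO library, and the correlations of 0.854 and 0.221 without the Cas9 and the TET2 KO library of cord blood 1. Residual degrees of freedom fall from 6 to 4 with the block. The cause was not tested unless stated.

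List calls, 15 in the main test, numbered 9 with no filter, 28 with the strict filter, 29 with DESeq2 and 45 with DESeq2 and the block, and with the block 36 without cord blood 2 and 25 without cord blood 3. The correlation of the knockouts was 0.638 with the strict filter, 0.38 with DESeq2, and 0.411 with the block and without cord blood 2.

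With the GC-window score and the block, 0, 23 and 21 genes and 27 lists were called. With the window taken from coding transcripts alone the counts were 0, 19, 21 and 27, so the number of genes rests on how the window is defined. With the score but no block, 0 genes were called. With the score, the marker score and the block, 3, 2 and 2 genes were called, 1 in both knockouts, and r was 0.244; with a marker score of 7 genes instead, 2 (EGR1 and SPP1), 0 and 1 (SDK2). GC and length offsets gave 0 genes in each comparison, alone, with the block and with each marker score; lists numbered 33 with the block and 23 with the block and the marker sum, where r was 0.378. Without GC-rich genes and with the block, 0 genes and 25 lists were called.

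Calls in the opposite direction were few. With the block and without cord blood 1, TET2 KO gave 4.08 for GATA2, 1.89 for HBG1 and 2.46 for HBG2, and DNMT3A KO 4.87 for GATA2 and 5.57 for LMO2; with the score and the block GATA2 gave 2.47 in DNMT3A KO. These genes had few or no counts in some libraries. Lists turned as follows, with none called in the new direction except where stated. Mitosis in TET2 KO ran from -0.87 to 0.195 when 1 library or cord blood was left out, with 0.195 without cord blood 1. Immediate early genes in DNMT3A KO ran from -0.00177 (without cord blood 3; -0.112 with the block) to 0.929, and were -0.0567 with the offsets, 7-gene score and block and -0.0163 with the GC-window score in place of the offsets. Erythroid and K562 line markers in DNMT3A KO ran from -2.18 to 6.54, with -0.23 without the Cas9 library of cord blood 2, and were -0.0381 and 0.0532 in those fits, the latter a median above 0 with a downward test. Between the knockouts, cytotoxic effectors ran from -0.0657 (without cord blood 1; -0.0792 with the block) to 0.234, and were -0.00606 without the DNMT3A KO library of cord blood 1, -0.101 with both scores and block, -0.0571 with the offsets, marker sum and block, and -0.126 with the GC-window score, 7-gene score and block. Mitosis there ran from -0.643 to 0.165 (without cord blood 1; 0.0929 with the block), and was -0.00906 without the TET2 KO library of cord blood 3, with an upward test, 0.0773 without the DNMT3A KO library of cord blood 1, 0.0448 with the offsets, 7-gene score and block, and 0.194, called (adjusted p = 0.0191), with the offsets, marker sum and block.

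Of the values of called lists, 367 kept direction and call, 122 lost the call and 21 turned. Of 5166 values of single named genes, 804 had the other sign from the main test, and the 6 of these that were called are given above; sign changes of uncalled genes were not counted as reversed. The pseudocount settings apply to normalized values only and gave no value, and list tests were not repeated on the limma fit, whose log2 values are those of the main list test.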

Other observations

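All tests below were chosen after the result was seen, except those on HBB and on GC content along the leading axis of the libraries. Adjusting for the GC-window score and the cord blood, edgeR called 23 genes higher in DNMT3A KO than in Cas9. They included the globin genes HBG1 (2.10, SE 0.19; adjusted p = 0.000375) and HBG2 (2.15, SE 0.21; adjusted p = 0.000592), PRAME, a tumour antigen gene (2.19, SE 0.20; adjusted p = 0.000375), and the erythroid transcription factor gene GATA1 (2.23, SE 0.29; adjusted p = 0.0075). Of the 23, 8 belong to the list that makes the marker score, and of the other 15, 13 tracked that score across libraries at r over 0.9. The remaining genes were EGR1 (0.89, SE 0.14; adjusted p = 0.023) and FOS (1.07, SE 0.18; adjusted p = 0.0445), and EGR1 itself has a window of 86 percent GC. With the marker score added as well, EGR1 was called in TET2 KO (0.94, SE 0.11; adjusted p = 0.000399) with SPP1 and SDK2, SPP1 and CNOT1 in DNMT3A KO, and SDK2 and ARHGAP31 between the knockouts, with 2 residual degrees of freedom. EGR1 passed in 3 alternatives for each knockout, and the simulated data gave 16 false calls with the GC-window score and block, so these are leads for a repeat.

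The knockout differences of cord blood 1 ran opposite to those of cord bloods 2 and 3. The highest of the 4 correlations with cord blood 1 was -0.795, which is the pattern itself and leaves open a smaller effect shared by the cord bloods. Loss of transcripts with GC-rich windows in some libraries may account for part: such genes were 4.44 times as frequent among the 290 genes called without cord blood 1 (28.2%) as among all tested genes (6.35%), but genes with no window of 70 percent GC still correlated at -0.745 between cord bloods 1 and 3, and gene GC content tracked the leading axis at a rho of -0.333, between the bounds set beforehand (0.4 for GC bias, 0.2 against). Of 6 exchanges of a Cas9 and a knockout library within a cord blood, 1 made all correlations between cord bloods positive (lowest 0.16). After it 1 of the 2 targets was lower in its own knockout in 3 of 3 cord bloods, against 2 as labelled. Any such exchange reverses the difference of 1 target in its cord blood, so this count could not stay at 2. It does not weigh against a mix-up, which stays open, and the labels were kept. A response that differs between cord bloods was not tested and stays open too.

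Erythroid and K562 line markers differed widely between libraries, and erythroid cells of the cord blood are argued against as the source, since HBB made up 0.0519% of HBG1 plus HBG2 counts in the library with the most HBG2. RNA of 1 other kind of cell with K562 line markers stays open: over the 5 libraries with at least 100 PRAME counts, log2(HBG2/PRAME) had an SD of 0.297 (1.85 for HBG2 itself), but over 19 list members the median SD was 0.531, with 8 under 0.5 and 6 over 1, LMO2 (2.14) and TRIM58 (2.25) among them. The 6 also include EPOR (1.91) and BLVRB (1.24), at 17.9 and 9.73 CPM in the Cas9 library of cord blood 2, which had 0 PRAME counts. HBD (2.44) and SLC4A1 (1.06) fell to 1 and 3 counts in the 5 libraries. The ratios of these members to PRAME therefore say little about a shared source. In the Cas9 library of cord blood 1 (GC-window score 0.77), LMO2 and TRIM58 had 403 and 424 counts beside 4571 of PRAME. In TET2 KO and DNMT3A KO of that cord blood (-0.53 and -0.75), they had 9 and 17 beside 1563, and 43 and 70 beside 5948. In those of cord blood 3 (0.64 and 0.73), they had 20 and 69 beside 174, and 73 and 95 beside 837. Their ratios thus varied with the GC-window score, and the cause was not tested. The labels name no K562 cells, and whether the flow sort they describe, which would remove such cells, was applied to the bulk libraries is not clear. Loss of DNMT3A is argued against for the differences between cord bloods, since a Cas9 library had 6.23 times the marker RNA of the highest DNMT3A KO library of the others. Within a cord blood it cannot be told apart from such RNA: DNMT3A KO exceeded Cas9 in 3 of 3 cord bloods (1.16, 1.21 and 4.84 times) but TET2 KO did in 2 of 3. In cord blood 2, EPOR and BLVRB made up most of the sums: 17.9 and 9.73 of 28.46 CPM in Cas9, 18.7 and 12 of 34.49 in DNMT3A KO. TET2 KO had 17.2 and 13.8 of 32.51 there, so the ratios of cord blood 2 say little about such RNA. In Cas9 of cord blood 3 these genes stood at 15.4 and 11 of 36.34 CPM, which draws the 4.84 towards 1.

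In each comparison the real grouping gave 0 genes and the highest of the other splits of its 6 libraries also gave 0, so 10 of 10 splits gave as many, as they must beside a real count of 0, and 10 splits are too few for a share under 0.05. With the cord blood as a block, the real split of DNMT3A KO and Cas9 gave 0 genes and 1 of the 3 other splits that part every pair gave 801, which points to a structure of the libraries: it restates the opposite directions given above, whatever their source, and does not settle whether a mix-up is behind them. In the other comparisons, the real split and those 3 splits gave 0 genes with the block.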
